A study of Mus musculus with 8 samples.

How the data were processed

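RNA from 8 cultures of IL-6-treated, bone marrow-derived mouse macrophages, 4 Ctrl and 4 IL6raKO, was labelled with biotin and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The deposited table holds 1 log2 expression value per probe set and array for 35556 probe sets. RMA, a method of background correction, quantile normalization and summary of probes, and R 2.13.1 are named in the submitters' processing notes, while the order of steps, any further filter and the genome build are not given in the sources used here. The log2 scale of the deposited values was read from their range, 1.96 to 14.2, and from RMA being named. RMA compresses differences of dim probe sets, and the values of single probes were not analysed here. Values of every column were used, and no 2 arrays were alike beyond noise (the smallest SD of the log2 difference between any 2 arrays over genes was 0.16).

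Probe sets were named through a table of GEO's platform annotation with Entrez identifiers. Of the 35556 probe sets, 21789 (61.3%) had exactly 1 gene symbol, 1621 had several and 12146 were not named in it, controls included. The identifiers of 21698 probe sets were found in the RefSeq gene table of GRCm38.p6, which left their symbols unchanged. The table served for names and gene order only, and no coordinates are given because the array files name no build. For the 998 genes with more than 1 probe set, the one with the highest mean over all 8 arrays was used, which gave 19938 genes. For Irf1, Socs3 and Cd80, whose probe sets disagreed, both values are given. Among other list members, the used and another probe set differed for Cycs (0.05 and -0.71), Bnip3 (-0.18 and -0.01), Pkm (0.00 and -0.17), Top2a (-0.06 and 0.17) and Ighm (-0.17, with 0.01 and -0.06 for its others). A further gene was left out as the second Entrez identifier of a symbol.

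The comparison was IL6raKO minus Ctrl, with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3 on the values as deposited, all 8 arrays in 1 fit, no covariate, no filter on dim genes and Benjamini-Hochberg adjustment over all genes. Calls are at an adjusted p under 0.05, two-sided. Gene sets were 27 lists, with 414 of 448 entries measured and 12 entries on probe sets shared with other genes, tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Within each list, p-values were also adjusted over the list alone. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where an addition is stated. That rule took Il6ra and Lyz2, then up to 12 genes per direction, first the called genes without overlap between groups by size, then those of lowest unadjusted p, leaving out unnamed gene models, microRNA and snoRNA genes. Each list gives up to 4 members of lowest p, and other members are named as known examples chosen after their values were seen. The list of alternative activation genes and the entry of Il4ra were chosen with knowledge of the study's paper.

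On simulated data with 200 of 19938 genes changed, the same procedure recovered 77.2% of genes changed by 0.5 on the log2 scale and 99.3% of those changed by 1, with 5.3% and 5.4% of calls false. In 20-gene lists, camera called 50 of 50 lists shifted by 0.15 and 0 of 50 unshifted lists. Genes were simulated as independent, which real genes are not. With 200 changed genes the Benjamini-Hochberg cutoff is also looser than in the real data, where 6 genes were called. There, Il6ra with a difference of -0.50 was not called over all genes, so the recovered shares do not carry over. With no change simulated, 1 of 10 runs and 0 of 10 runs made any call.

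Replicates 1 to 4 of the groups share numbers in the labels. Alternatives were a trended and robust variance model, the replicate number as a block, filters at the median and at the 25th percentile of mean expression, quantile normalization and centring on the 75th percentile, array weights, the mean of a gene's probe sets, all probe sets, other thresholds, each array left out in turn, an estimated correlation in camera, and fry. A covariate of mast cell and basophil markers and the STAT3 list without its called members were added after seeing the data.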

Results

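Gene expression was measured in macrophages grown from mouse bone marrow with M-CSF (10 ng/ml) for 10 days, serum-starved overnight and then exposed to recombinant murine IL-6 (50 ng/ml) for 4 h. IL-6 is a cytokine that signals through the IL-6 receptor alpha chain, encoded by Il6ra, and the shared chain gp130 to the transcription factor STAT3. Control macrophages (Ctrl) came from mice with loxP-flanked Il6ra alleles, and Il6ra-deficient macrophages (IL6raKO) from mice that also carried LysM-Cre, a recombinase expressed in myeloid cells. Each group had 4 arrays, which the labels call biological replicates, and every array was from IL-6-treated cells. The comparison asks how the expression profile of IL-6-exposed macrophages differs between these genotypes. Only IL6raKO mice carried LysM-Cre, so loss of the receptor could not be told apart from other effects of Cre or its insertion. Without unstimulated arrays, a difference between genotypes could not be separated into a part that needs IL-6 and a part already present before it was added. The labels do not say that every replicate was a separate animal, so the p-values measure the spread between these 8 samples. Arrays carry no read depth, and their number limits the precision. The medians of the 8 arrays lay between 6.31 and 6.35 on the log2 scale.

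Il6ra, the targeted gene, fell by 0.50 on the log2 scale in IL6raKO macrophages (SE 0.07, 95% confidence interval -0.66 to -0.34), to 70.6% of the control level. Its log2 expression was 8.42 ± 0.02 (SD, n = 4) in Ctrl and 7.92 ± 0.14 (SD, n = 4) in IL6raKO, and each IL6raKO array lay below each Ctrl array. The adjusted p in limma was 5.5e-05 over the 2 genes fixed in advance as checks of the genotype (Il6ra and Lyz2) and 0.0607 over all 19938 genes. Lyz2, the lysozyme gene whose locus carries the Cre insertion, was at 13.17 ± 0.13 (SD, n = 4) in Ctrl and 13.07 ± 0.02 (SD, n = 4) in IL6raKO, a difference of -0.11 (95% confidence interval -0.27 to 0.05, limma adjusted p = 0.763 over all genes) that was within the replicate spread. Over the 2 fixed genes, the limma adjusted p of Lyz2 was 0.16. Its IL6raKO values, 13.04 to 13.1, lay below Ctrl replicates 1 to 3 (13.31, 13.18 and 13.21) and above Ctrl replicate 4 (13). Without Ctrl replicate 4 the difference was -0.17 (limma adjusted p = 0.733 over all genes). As a check of the genotype, Lyz2, at percentile 100 of mean expression, thus did not tell the groups apart in the fit of all arrays. The 1 Il6ra probe set sums probes over the transcript, and which of them lie in the deleted part was not analysed here.

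A small set of genes was lower in IL6raKO macrophages. At an adjusted p under 0.05 in limma, 6 of 19938 genes were called, all 6 lower in IL6raKO and 0 higher. They were Nxpe5 (fell by 0.59, SE 0.07), Casp4 (fell by 0.59, SE 0.06), Stat3 (fell by 0.57, SE 0.07), Olfm1 (fell by 0.52, SE 0.07), Il4ra (fell by 0.52, SE 0.07) and Olfr676 (fell by 0.45, SE 0.06), with adjusted p between 0.0276 for Casp4 and 0.0475 for Olfm1 and Olfr676. Stat3 is the transcription factor downstream of the IL-6 receptor and stood at 67.3% of its control level. Il4ra, the receptor chain shared by IL-4 and IL-13, stood at 69.9%, and Casp4, the mouse caspase-11 that senses intracellular lipopolysaccharide, at 66.6%. Olfm1 encodes a secreted olfactomedin, and Olfr676 an olfactory receptor that was dim on these arrays (5.49 in Ctrl, 5.03 in IL6raKO). No gene differed by 1 or more on the log2 scale (0 of 19938).

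Leaving out any 1 of the 8 arrays, which also lowers the number of samples, reduced the count of called genes to 0 or 1. It was 0 without any 1 of the 4 Ctrl arrays and without IL6raKO replicate 3 or 4, and 1 without IL6raKO replicate 1 or 2. Ctrl replicate 4 lay at 21.5 on the first principal component while the other arrays lay between -6.6 and 4.8, but leaving it out was not particular in giving 0. Testing all 35556 probe sets in limma also gave 0, with 923 probe sets without a single gene name at an unadjusted p under 0.05. With any 1 array left out, the 6 differences lay between -0.65 and -0.42. Quantile normalization applied again gave 9 genes, 8 lower and 1 higher, and ended the call of the dim Olfr676 (-0.41, adjusted p = 0.124). At an unadjusted p under 0.05 in limma, 1452 genes differed (905 lower and 547 higher), where chance gives about 997 on average. Genes are not independent, so a single grouping can lie far from that average. Other splits of the 8 arrays into 4 and 4 gave up to 1373. The 4 IL6raKO values lay entirely below the 4 Ctrl values for 2.37% of genes and entirely above for 2.07%, against 1.43% by chance in each direction.

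**Figure D1:**
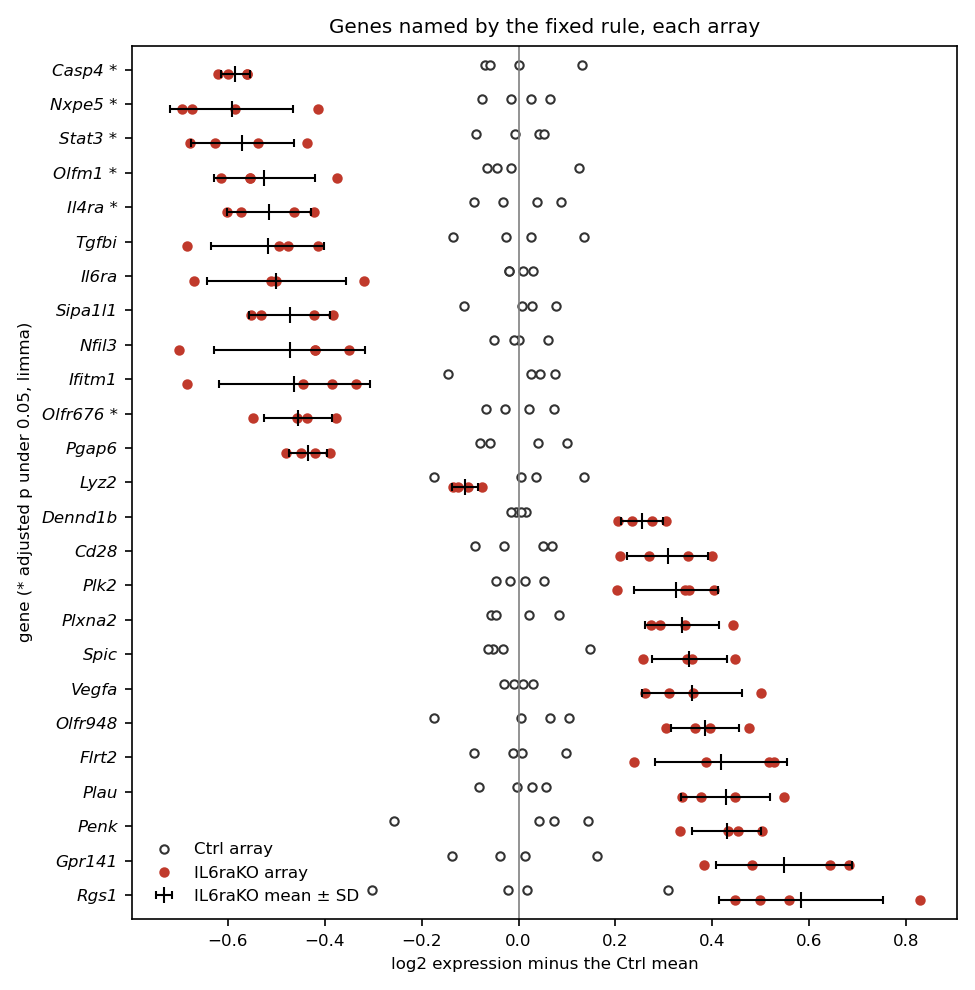
The 25 genes named by the rule fixed in advance, with the log2 expression of each array minus the Ctrl mean on the x axis (open circles Ctrl, filled circles IL6raKO, bars the IL6raKO mean ± SD, n = 4). Stars mark the 6 genes past an adjusted p of 0.05; except for Lyz2, the values of the 2 genotypes do not overlap.

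Other genes with low p-values in the lower direction did not pass the threshold over all genes. Sipa1l1, a Rap GTPase-activating protein, differed by -0.47 (SE 0.07) and Pgap6 by -0.43 (SE 0.06), each with a limma adjusted p of 0.0501. Tgfbi, an extracellular matrix protein, differed by -0.52 (SE 0.08, adjusted p = 0.0727), Nfil3, a basic leucine zipper transcription factor, by -0.47 (SE 0.08, adjusted p = 0.121), and Ifitm1, a membrane protein of the interferon-induced transmembrane family, by -0.46 (SE 0.09, adjusted p = 0.237). In the higher direction the lowest adjusted p was 0.078, for Plau (difference 0.43, SE 0.07), which encodes the urokinase plasminogen activator, and for Gpr141, an orphan receptor (0.55, SE 0.09). Vegfa, the endothelial growth factor, was 0.36 higher (SE 0.07), the adhesion protein Flrt2 0.42, the semaphorin receptor Plxna2 0.34, the kinase Plk2 0.33, Spic, a transcription factor of iron-recycling macrophages, 0.35, the enkephalin precursor Penk 0.43, Rgs1, a regulator of G-protein signalling, 0.58, Dennd1b 0.25 and the costimulatory receptor Cd28 0.31. Olfr948, at the very low level of 2.95 in Ctrl, was 0.38 higher. The adjusted p of these 10 genes lay between 0.237 and 0.369.

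Of the 20 measured targets of STAT3, 17 were lower in IL6raKO macrophages, and the call of the list as a group depended on the test. Of these 20 members, 13 did not pass and 7 passed when adjusted over the list alone, 6 lower and 1 higher, and 2 (Stat3 and Il4ra) passed over all genes. Beside Stat3 and Il4ra, the members that fell over the list alone were Nfil3, Bcl3 (fell by 0.38, SE 0.07), an atypical IκB protein, Sbno2 (fell by 0.28, SE 0.08), a corepressor of the IL-10 pathway, and Socs3 (fell by 0.27, SE 0.08), the feedback inhibitor of gp130 signalling, of which a second, dimmer probe set differed by -0.08. Fos, an immediate early transcription factor, rose by 0.30 (SE 0.07). Other known targets did not pass: Pim1 differed by -0.03, Cebpd by -0.06, Junb by 0.05, Icam1 by -0.03 and Timp1 by -0.03. The median difference of the list was -0.09 and its mean -0.14, and limma's camera with its preset correlation called the list (adjusted p = 0.00023 over 27 lists). The call was lost with an estimated correlation (adjusted p = 0.58 with an estimated correlation) and with fry's directional test (adjusted p = 0.052). Il4ra was entered into this list with knowledge of the study's own interest in it, so its fall is not independent evidence; without Il4ra the camera adjusted p was 0.0047, and without Stat3 and Il4ra it was 0.079.

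**Figure D2:**
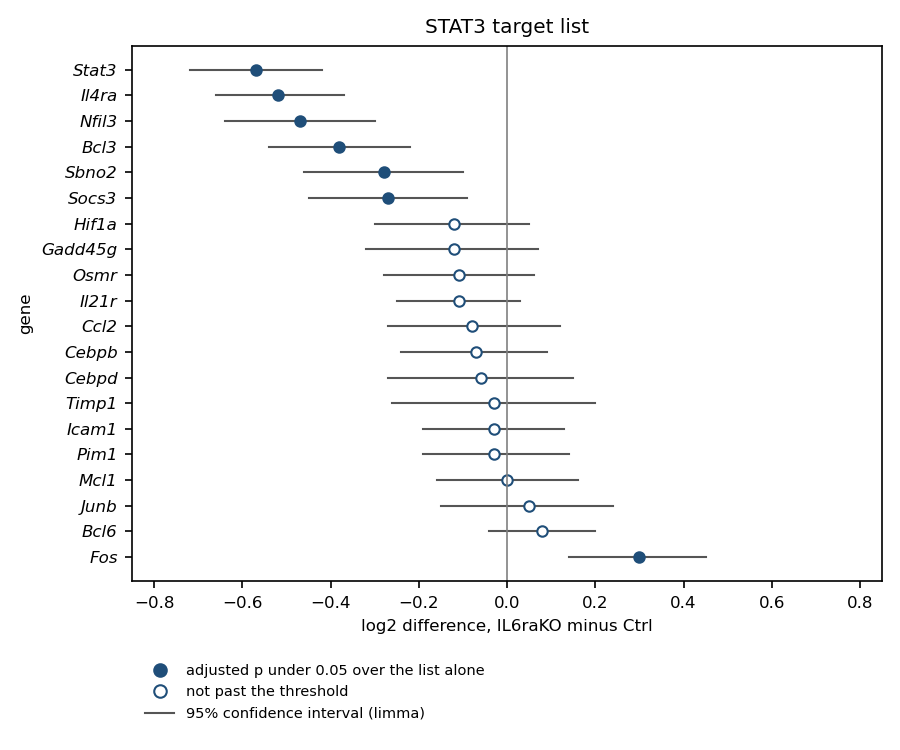
Log2 difference (IL6raKO minus Ctrl, x axis) of the 20 measured STAT3 targets, with 95% confidence intervals from limma. Filled points are the 7 genes past an adjusted p of 0.05 over the list alone: Stat3, Il4ra, Nfil3, Bcl3, Sbno2 and Socs3 lie below 0 and Fos above.

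Among 17 measured receptor chains, kinases and inhibitors of the IL-6 family pathway, 3 passed when adjusted over the list alone, Stat3, Il6ra and Socs3, all 3 lower, and 1 (Stat3) passed over all genes. The other 14 did not pass. Il6st, which encodes gp130, differed by 0.09 (95% confidence interval -0.06 to 0.23) and Jak1 by -0.01 (95% confidence interval -0.14 to 0.11). The list was not called as a group (camera adjusted p = 0.21), while fry's mixed test, which asks whether members change in either direction, gave an adjusted p of 7.8e-06. A few members can carry the mixed test, and this list holds Il6ra, the targeted gene itself, and Stat3. Of 20 measured genes of alternative activation, the state that IL-4 induces, only Il4ra passed, over the list alone and over all genes. The effector genes of this state did not: Arg1, arginase 1, differed by 0.09 (95% confidence interval -0.06 to 0.24), Mrc1, the mannose receptor, by -0.01 (95% confidence interval -0.16 to 0.14), Retnla by -0.08 and Chil3 by -0.17. This list too was chosen with knowledge of the study, so its count is not independent evidence. Its median was -0.05 (camera adjusted p = 0.41, fry mixed adjusted p = 0.0017).

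Anti-inflammatory and feedback genes moved in both directions. Of 15 measured genes of this IL-10 type list, 6 passed over the list alone and 0 over all genes. Nfil3, Bcl3, Sbno2 and Socs3 fell, and Dusp1, a phosphatase that inactivates MAP kinases, rose by 0.25 (SE 0.07), as did Il1rn, the IL-1 receptor antagonist, by 0.28 (SE 0.08). Il10 itself differed by 0.00 (SE 0.07) at the low level of 4.73. The camera adjusted p was 0.85 (median 0.03, mean -0.04, so that the 2 differ in sign), and the fry mixed adjusted p was 2.3e-06. The 4 members that fell over the list alone are also in the STAT3 list, whose fry mixed adjusted p was 3.1e-05, so these are not separate results. The lists share other members too: Dusp1 is also an immediate early gene below, and Fos is also in the STAT3 list. Of 16 measured immediate early and heat shock genes, 4 passed over the list alone, all higher: Egr2 rose by 0.32 (SE 0.08), Fos by 0.30, Dusp1 by 0.25 and Jun by 0.21. Egr1 differed by 0.01 and the heat shock gene Hspa1a by 0.12. As a group this list was not called (median 0.03, camera adjusted p = 0.16, fry mixed adjusted p = 0.00083), and camera gave an adjusted p = 0.79 with an estimated correlation. With the preset correlation it was called without IL6raKO replicate 1 (median 0.01, adjusted p = 0.042) and with a covariate of mast cell and basophil markers, added after seeing the data (0.06, adjusted p = 0.022).

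Most inflammatory genes did not pass the test. Of 23 measured genes, 2 passed over the list alone and 0 over all genes: the neutrophil chemokine Cxcl2 rose by 0.35 (SE 0.08) and Il1a by 0.25 (SE 0.07). Tnf differed by 0.07 (95% confidence interval -0.13 to 0.27) and Il1b by -0.10 (95% confidence interval -0.34 to 0.14). The list's median was -0.07 (camera adjusted p = 0.93, fry mixed adjusted p = 0.0031). Of 25 measured interferon-stimulated genes 0 passed over the list alone, and the lowest p-values were those of Gbp5 (-0.38, SE 0.10, adjusted p = 0.0513 over the list in limma), Irf1 (-0.22, SE 0.07) and Gbp3 (-0.28, SE 0.10). A second Irf1 probe set differed by 0.00. Camera gave an adjusted p of 0.94 for this list (median 0.01, mean -0.01) and fry's mixed test 0.031. Of 10 measured genes of MHC class II and antigen presentation 0 passed, with Cd80, a costimulatory ligand, at 0.28 (SE 0.10, a second probe set at 0.04) and H2-Ab1 at 0.19 (SE 0.11), and the list was not called (median 0.10, camera adjusted p = 0.20, or adjusted p = 0.79 with an estimated correlation) in the fit of all arrays. With the preset correlation it was called without IL6raKO replicate 1 (median 0.17, adjusted p = 0.041) and with a covariate of mast cell and basophil markers, added after seeing the data (0.15, adjusted p = 0.02).

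Metabolic, stress and growth programmes were not called as groups. In camera, with the median difference in each case, the adjusted p was 0.93 for 26 cell cycle genes (-0.05), 0.85 for 18 genes of glycolysis and hypoxia (-0.02), 0.85 for 26 of oxidative phosphorylation (-0.02), 0.85 for 16 of sterol synthesis (-0.02), 0.79 for 19 of LXR and lipid handling (0.01), 0.43 for 18 of endoplasmic reticulum and amino acid stress (0.03) and 0.85 for 13 of the NRF2 response (0.04). Within them, Vegfa rose over the list alone and Gsr, glutathione reductase, fell by 0.27 (SE 0.06). The fry mixed adjusted p was 0.0016 for glycolysis and hypoxia and 0.023 for the NRF2 response, and 0.1 or higher for the other 5 lists. The list of 22 macrophage identity genes had a median of -0.01 (camera adjusted p = 0.85) and 0 of them passed.

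In the fit of all 8 arrays and all genes with no covariate and no block, markers of other cell types did not pass in any list, over the list alone or as a group. The mast cell, basophil and eosinophil markers had the lowest camera p among them (14 genes, median -0.11, adjusted p = 0.14, or adjusted p = 0.79 with an estimated correlation), and 13 of the 14 were lower in IL6raKO. Among the alternatives, this list was called among genes above the median level (median -0.18, adjusted p = 0.019), among the brightest 75% of genes (-0.15, adjusted p = 0.029), without Ctrl replicate 1 (-0.14, adjusted p = 0.016) and without IL6raKO replicate 4 (-0.15, adjusted p = 0.0042). It was also called with the replicate number as a block (-0.11, camera adjusted p = 0.0016), although over all genes the numbers did not pair the arrays. All these calls used the preset correlation. Mcpt8, a basophil protease, was at 7.60 ± 0.62 (SD, n = 4) in Ctrl and 7.14 ± 0.67 (SD, n = 4) in IL6raKO, and Cpa3, a mast cell and basophil carboxypeptidase, at 8.44 ± 0.52 and 8.07 ± 0.49 (SD, n = 4 each). With the mean of these markers as a covariate, an analysis added after seeing the data, 0 genes passed over all genes in limma. The B cell list was then called with the preset correlation (median -0.08, camera adjusted p = 0.041). Without the covariate its camera adjusted p was 0.14 with the preset correlation and 0.58 with an estimated one. The median difference of the 6 called genes was -0.51 with the covariate and -0.55 without it. The medians of the other marker lists were -0.09 for 9 B cell genes (adjusted p = 0.14), -0.11 for 8 monocyte genes (0.29), -0.09 for 15 neutrophil and granulocyte precursor genes (0.57), -0.05 for 12 stromal genes (0.79), -0.02 for 15 T and NK cell genes (0.79), 0.01 for 11 dendritic cell genes (0.85), 0.02 for 10 osteoclast genes (0.85) and 0.02 for 6 erythroid and megakaryocyte genes (0.93). The 6 small and long non-coding RNAs kept as signs of RNA quality had a median of 0.10 (adjusted p = 0.20). Of 4 sex-linked genes, Xist fell by 0.34 over the list alone, at the low level of 4.90 in Ctrl and 4.57 in IL6raKO, and the Y-linked Eif2s3y was well expressed in both groups (9.04 and 9.25; list adjusted p = 0.79).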

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

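The tests on Ctrl replicate 4 below were chosen after its position among the arrays was seen. Among 104 sets of 4 values, 1 per gene or list and genotype, 2 held an array far from the other 3, where chance gives about 5.2. Spic, a transcription factor of iron-recycling macrophages, was at 7.15 in Ctrl replicate 4 and between 6.94 and 6.97 in the other Ctrl arrays. The median of the sex-linked list, relative to the means of all 8 arrays, was -0.21 in Ctrl replicate 4 and between 0 and 0.03 in the other Ctrl arrays.

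Both values come from Ctrl replicate 4, which also stood apart on the first principal component (23.6% of the variance). Its mast cell and basophil markers were high: relative to the other arrays, Cpa3 differed by 1.04, Mcpt8 by 1.1 and Ms4a2 by 0.76, and the list's median deviation of 0.23 lay at percentile 100 of 10000 random lists of matched expression, as RNA of such cells in that culture would give. The neutrophil list lay at percentile 99.7 and the STAT3 list at 98.8 in the same array, so the markers were not alone. Noise of that array may contribute as well, since the spread of its deviations was the largest of the 8 arrays among the dimmest genes (1.11 times the median of the others), but it was further from the others among the brightest (1.64 times). Both explanations stay open, and the design gives no biological difference to test, since the labels put this array in the same group as the other Ctrl arrays.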

How the results depend on the processing

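The covariate of mast cell and basophil markers and the STAT3 list without its called members were chosen after the data were seen. The number of genes called (6) was 22 with a trended and robust variance model (16 lower, 6 higher), 11 among genes above the median level (10 lower, 1 higher), 11 among the brightest 75% (9 lower, 2 higher), 12 at an adjusted p under 0.1, and 0 in limma over every probe set or with the covariate. It was 8 or 9 under other normalizations, array weights or probe set means, and 0 to 1 with any 1 of the 8 arrays left out, where the highest unadjusted limma p of the 6 genes was 7.68e-05. The single calls there, chosen after their values were seen, were Nxpe5 (without IL6raKO replicate 2) and 3830403N18Rik, which was higher (without IL6raKO replicate 1). Fewer genes tested or fewer samples are part of the filter and left-out settings, and the cause was not tested for the others. Over the alternatives, the comparisons of the named genes with their reported values gave 325 on the same side of the threshold, 60 that fell short of it, 35 that passed it and 0 reversed.

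With the replicate number as a block the count was 0. By the check over all genes the numbers did not pair the arrays. The deviations of same-numbered arrays correlated at -0.01, -0.01, 0.04 and -0.01 over genes, and 1 of 4 pairs matched its own number best. The mean of the mast cell, basophil and eosinophil markers did follow the number, though not every member of that list did. The block called the mast cell, basophil and eosinophil markers in camera with the preset correlation (median -0.11, adjusted p = 0.0016). Without the block, their camera adjusted p was 0.14 with the preset correlation and 0.79 with an estimated one.

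Il6ra passed over all genes with the trended model (-0.50), among genes above the median level (-0.50), in the brightest 75% (-0.50), with quantile normalization (-0.53) and with centring on the 75th percentile (-0.53), and lay between -0.56 and -0.45 with 1 array left out, with adjusted p from 0.0528 to 0.222. Lyz2 kept its side of the threshold throughout.

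The STAT3 list lost its call with an estimated correlation (median -0.09, adjusted p = 0.58), in fry's directional test (-0.09, adjusted p = 0.052) and without Stat3 and Il4ra (-0.08, adjusted p = 0.079). Lists gained a call with the covariate for antigen presentation (0.15, adjusted p = 0.02), immediate early genes (0.06, adjusted p = 0.022) and B cell markers (-0.08, adjusted p = 0.041, all 3 with the preset correlation), and for mast cell and basophil markers above the median level (-0.18) and the brightest 75% (-0.15). With 1 array left out, medians ranged from 0.02 to 0.17 for antigen presentation, from -0.01 to 0.07 for immediate early genes and from -0.15 to -0.06 for mast cell and basophil markers. Without these changes and with the preset correlation, the camera adjusted p was 0.14 for B cell markers and for mast cell and basophil markers. It was 0.2 for antigen presentation and 0.16 for immediate early genes. With an estimated correlation it was 0.58 for B cell markers and 0.79 for the other 3 lists. Among the fits with 1 array left out, calls were gained without IL6raKO replicate 1 for antigen presentation (adjusted p = 0.041) and immediate early genes (adjusted p = 0.042). For mast cell and basophil markers they were gained without Ctrl replicate 1 (adjusted p = 0.016) and without IL6raKO replicate 4 (adjusted p = 0.0042). The cause was not tested.

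In 49 cases the small median of a list that was not called changed sign or came to 0. With centring on the 75th percentile it was -0.02 for interferon-stimulated genes, -0.02 for LXR, 0 for immediate early genes, -0.01 for dendritic cell, -0.01 for osteoclast and -0.01 for erythroid markers. With the covariate it was -0.02 for interferon-stimulated genes, 0.02 for cell cycle, 0.01 for oxidative phosphorylation, -0.01 for LXR, 0.02 for neutrophil, -0.04 for dendritic cell and 0 for osteoclast markers, and 0 for mast cell and basophil markers by construction. With quantile normalization it was -0.01 for interferon-stimulated genes and 0.02 for T and NK cell markers, among genes above the median level 0 for inflammatory genes and 0.01 for T and NK cell markers, and with array weights -0.03 for dendritic cell markers. With 1 array left out, ranges were -0.06 to 0 for the IL-6 receptor list, -0.02 to 0.04 for IL-10 type, -0.02 to 0.03 for interferon-stimulated, -0.07 to 0.01 for cell cycle, -0.03 to 0.01 for oxidative phosphorylation, -0.05 to 0.01 for sterol, -0.02 to 0.03 for LXR and -0.02 to 0 for macrophage identity genes. For markers they were -0.12 to 0.01 for neutrophil, -0.04 to 0.04 for dendritic cell, -0.04 to 0.03 for osteoclast and -0.03 to 0.06 for erythroid. Dim genes, whose signal is close to background, limit what these arrays can show.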

Other observations

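The interferon-induced transmembrane genes, the tests of Ctrl replicate 4 and of the markers against the 6 genes, the tests of the partial fall of Il6ra, and the pairing of markers by replicate number were chosen after the values were seen. The predictions for the splits, the flanking DNA and the ERK list were not. Of the interferon-induced transmembrane genes, which encode membrane proteins that restrict virus entry, 3 lay entirely lower in IL6raKO without passing over all genes: Ifitm1 (-0.46, limma adjusted p = 0.237), Ifitm2 (-0.33, adjusted p = 0.237) and Ifitm3 (-0.36, adjusted p = 0.303). Ifitm5 (-0.07), Ifitm6 (0.04), Ifitm7 (-0.02) and Ifitm10 (0.03) did not separate. These genes are close paralogs, and whether their probe sets share signal was not analysed here.

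The mean of the mast cell, basophil and eosinophil markers varied with the replicate number, as did Cpa3 and Mcpt8 among them. Not every member did. Siglecf was at 7.81, 7.67, 7.72 and 7.8 in Ctrl and at 7.84, 7.66, 7.64 and 7.78 in IL6raKO. Tpsb2 was at 5.81, 5.86, 5.64 and 5.88 in Ctrl and at 5.7, 5.6, 5.67 and 5.73 in IL6raKO. Cpa3 was at 7.93, 8.26, 8.42 and 9.17 in Ctrl replicates 1 to 4 and at 7.39, 8.08, 8.25 and 8.55 in the IL6raKO replicates of the same numbers, and Mcpt8 at 6.87, 7.37, 7.81 and 8.33 and at 6.19, 7.2, 7.52 and 7.67. Of the 24 ways to pair the arrays, 1, the real numbers, gave a covariance of the marker mean as high. That outcome follows from the rise with the number in both groups, which prompted the test, so it adds no separate support. Cultures of one number may share their content of these cells, although the numbers did not pair the arrays over all genes. The marker mean was lower in IL6raKO in each of the 4 same-numbered pairs (-0.17, -0.15, -0.08 and -0.19).

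The count of 6 genes lower in IL6raKO stood out from other groupings of the arrays, which argues against a chance split for that count. Of the 35 splits of the 8 arrays, 1, the real one, gave as many called genes (6, highest other 0, with 1452 genes at an unadjusted p under 0.05 against at most 1373), and 1, the real one, a camera p of the STAT3 list as small (8.6e-06, lowest other 4.2e-05). A rank of 1 among 35 is the best this test can give. The lowest other p came from swapping Ctrl replicate 2 with IL6raKO replicate 3, so the list stood out by little. Il4ra was also entered with knowledge of the study, so the splits do not decide on the list. Its p uses the preset correlation: the call of the list was lost with an estimated correlation (adjusted p = 0.58) and without Stat3 and Il4ra (adjusted p = 0.079). The median difference of the 6 genes, -0.55, was -0.52 without Ctrl replicate 4 and -0.51 with the marker covariate (median SE 0.07 without and with the covariate). The differences thus did not rest on that array alone. The 6 genes were picked in these data for differences large against their replicate spread, so neither fit was likely to move them much. These fits therefore do not decide whether fewer mast cells or basophils contributed. The covariate, which takes a degree of freedom, ended the calls (lowest adjusted p 0.0863 in limma). None of the 6 (0) lay among the 40 measured genes nearest to Il6ra or to Lyz2, in the gene order of GRCm38.p6. For these 6 genes, this argues against a local effect of flanking DNA of another strain. The median absolute difference reached percentile 64.5 of 10000 random sets at Lyz2 and 5.5 at Il6ra. Both groups carried loxP-flanked Il6ra alleles, so the Il6ra locus could not decide on flanking DNA. Near Lyz2, the 4 genes at an unadjusted limma p under 0.05 were all higher: Slc35e3 (0.41), Lyz1 (0.32), Mdm2 (0.19) and Yeats4 (0.18). None of them was called over all genes, and flanking DNA at Lyz2 stays open for them. A hypothesis that stays open is that lower IL-6 signalling lowers the 6 genes. An effect of Cre or its insertion cannot be told apart from it. Whether the 6 genes differ before IL-6 is added was not analysed here.

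Il6ra fell only in part. Its IL6raKO mean lay at percentile 74.9 of all genes, which argues against the floor of the arrays as the reason. Probes outside the deleted part and incomplete deletion cannot be told apart with 1 probe set and no values per probe.

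Immediate early genes that passed over their list were higher in IL6raKO, and more ERK signalling was a hypothesis for it. The prediction was that a list of 19 measured ERK feedback genes, without members of the immediate early list, would be higher. With the preset correlation it was (camera p = 0.016, not adjusted over lists), but not past 0.05 with an estimated correlation (p = 0.17). The median was small, 0.04, with 11 genes higher and 8 lower. Only 1 passed over the list alone, Plaur (0.36), while Spry1 (0.23), Dusp6 (0.04), Spry4 (0.04) and Dusp5 (-0.12) did not. Because the result depended on the correlation used, it does not decide whether ERK signalling was higher.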
